A study of Homo sapiens with 33 samples.

How the data were processed

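RNA of THP-1 and CaCo-2 cells was reverse transcribed with a radioactive label and hybridised to nylon membranes carrying 34560 cDNA spots, per the labels' protocols. The deposited values are array intensities on a linear scale, as read from the values. Image analysis, background treatment and normalization are not given in the sources used here. From the values, the 22 single columns have an SD between 1.36 and 1.38 and a highest value between 133 and 145, so that some scaling between arrays preceded deposit. Values of -1 or lower multiples occur at between 46 and 335 spots per column and were read as codes for excluded spots. The meaning of an exact 0 is not given in the sources used here.

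Of the 33 columns, 11 lie at about 3 times the scale of the others. For 10 of these, the value was at least double that of 1 particular single column at 99.6% or more of its positive spots, against at most 82.5% for any other single column, and at 100% of the spots where the summed column was 0 the single column was 0 too. Both were taken as the sum and the median of the same 3 component values. In 1 of the 10 pairs the summed column is labelled CaCo-2 control and the single column CaCo-2 TNF, and both were left out. The other 9 pairs were counted once through their single column, since 12 further arrays have only that kind of column and a mean would mix both kinds unequally between groups. The mean of both was run as an alternative. THP-1 control replicate 3 is a summed column with no partner. It held 0 at 32.1% of spots, like a single column, against 17.2% to 22.3% in the other summed columns. Its values were divided by 3. These choices depart from the planned fit of all 33 columns. They were made after the columns' structure was seen and before any test was run.

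Excluded spots were set to missing, where the plan would have raised them to the floor. Values at 0 were raised to the lowest positive value of the array, as planned before the data were examined, and log2 was taken. Array medians departed from their middle by -0.30 to 0.24, beyond the planned tolerance of 0.1, so the arrays were quantile normalized. The rule for 0 proved doubtful once the values were plotted. In 9 pairs, at 822 readings of spots that read over 0.4 on other arrays of the line and 0 in the single column, the summed column still held a value, with a median between 0.829 and 0.982 times that level, which is the size of 1 component. At 609 further such readings the summed column was 0 as well. A value of 0 thus does not place a spot below the dimmest measured ones. The planned fit was kept as the main one, and fits with 0 as missing, or with only spots above 0 on every array, were added after seeing the data and are given beside it.

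Tests used lmFit and eBayes with a variance trend in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all spots and a threshold of 0.05. The CaCo-2, THP-1 and cell line comparisons used only their own groups, and the interaction used all 22 arrays. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Each gene was represented by its brightest spot over all 33 columns, and lists with fewer than 5 measured genes were only described. This left 17 of the 18 lists for testing, since 4 lymphocyte markers were measured.

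Of the spots, 18025 carry 1 gene symbol, 858 carry several and 15677 are unnamed in the platform annotation. Entrez identifiers of 17928 spots were in the human reference table (assembly GRCh38.p14), for 10706 genes, and 0 symbols changed. No gene was named from a spot with several symbols. Named genes followed a rule fixed before the data were examined: per comparison, up to 8 genes with the largest increase and 8 with the largest decrease past the threshold, or the 4 with the smallest p in a direction where none passed, a fixed set of TNF and cell line genes, and up to 4 members per list with the smallest p. A selection of these is printed.

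Alternatives comprised other normalizations, a filter on dim spots, array weights, no variance trend, each array left out, the replicate number as a block, all groups in 1 fit, a gene-level mean and a Welch comparison of calls. Alternatives added after seeing the data concern the codes, the paired columns, the pair with opposite labels, values at 0 and residual components as covariates. The covariates were first tried after the TNF counts had come out low. They were tried on all spots and on spots above 0 on every array. Besides the left-out arrays, 22 settings were run, the main one included, and 136 model fits in all.

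The fit was tested on simulated arrays with the means and spread of the real ones and 200 changed spots among those above 0 on every array. In the CaCo-2 simulation of 34560 spots, 88.1% of spots changed by 0.5 on the log2 scale, 95.5% of those changed by 1 and 100% of those changed by 2 were recovered. In the THP-1 simulation all 3 sizes were recovered at 100%. At 0.5, recovery was 85.1% for the interaction and 92.5% between the lines. Between 14 and 19 unchanged spots were called beside the changed ones. With no spot changed, 0 were called in each of the 4 comparisons. The simulation holds no structure shared between arrays and no readings lost to 0. It also changes 200 spots at once, which eases the adjustment, so recovery of only a few changed spots was not tested.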

Results

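The series holds cDNA membrane arrays of 2 human cell lines. THP-1 is a monocytic leukaemia line grown in suspension, and CaCo-2 is a colon carcinoma line with epithelial features. Each line was either left unstimulated or exposed to tumour necrosis factor alpha (TNF), an inflammatory cytokine, at 5 ng per ml for 60 min. The table lists 33 columns of 34560 spots: 7 THP-1 control, 8 THP-1 TNF, 10 CaCo-2 control and 8 CaCo-2 TNF columns. The columns are not 33 separate arrays, because 10 summed columns carry the same readings as 10 single columns. After each pair was counted once, and the pair that stands under both a CaCo-2 control and a CaCo-2 TNF label was left out, 5 THP-1 control, 7 THP-1 TNF, 5 CaCo-2 control and 5 CaCo-2 TNF arrays remained. Nothing in the labels says whether these arrays come from separate cultures, so p-values measure only the spread between arrays, which may be technical. The number of arrays limits the precision of every value given here. Levels are log2 intensities after quantile normalization, and errors are SD over arrays or SE of a log2 fold change.

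An exact 0 stands at between 32.1% and 39.6% of the spots of each array used. It was most frequent at low level but not confined to it. Among spots that read up to 0.15 in intensity on other arrays of the group, between 29.1% and 36.0% of readings were 0. Between 0.3 and 0.5 it was 10.2% to 15.3%, and above 1 at most 0.0666%. For genes listed at 0 on every array of a group, the level of the other group is therefore given without a fold. The value set for 0 leaves such a group without spread, so the p-values of these genes rest on that rule and can be far too small.

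The first comparison asks which transcripts differed after TNF in CaCo-2 cells. Among genes with a spot of their own, DIRAS3, a Ras-related GTPase, read -1.76 ± 0.02 (SD, n = 4) after TNF and was listed at 0 on all 5 control arrays. NMRK1, a nicotinamide riboside kinase, read -2.44 ± 0.07 (SD, n = 5) after TNF and was likewise at 0 on all 5 control arrays. The same held for PANTR1, a long non-coding RNA, at -2.47 ± 0.08 (SD, n = 5), and for CFC1, a Nodal co-receptor, at -2.88 ± 0.07 (SD, n = 5). Their adjusted p in limma were 6.77e-05 for DIRAS3, 0.000542 for NMRK1, 0.000657 for PANTR1 and 0.00558 for CFC1. In THP-1 control cells, DIRAS3 was above 0 on 2 of 5 arrays.

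In all, limma called 15 of 34560 spots in CaCo-2, 9 higher and 6 lower after TNF, and all 15 were at 0 on every array of 1 group. At an unadjusted p under 0.05 there were 1455 spots, against 1728 if p-values were evenly spread, which values tied at 0 need not give. This count was 856 without normalization and 2275 with all 4 groups in 1 fit, so it does not place the signal below or above chance. Among the 7966 spots above 0 on every array of the fit, 0 passed and 193 had an unadjusted p under 0.05. With values at 0 taken as missing, 0 of 25624 spots passed and 725 had an unadjusted p under 0.05. Neither fit could test the 15 called spots, each at 0 throughout 1 group. No gene passed in the downward direction among genes represented by 1 spot. Of the 4 with the smallest p, which missed the threshold, ABCA13, a lipid transporter family member, was measured on all arrays with a log2 fold change of -0.24 ± 0.06 (SE) and an adjusted p of 0.561 in limma.

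Of the 17 TNF response genes fixed in advance, 4 had a spot of their own: TNF, JUNB, IER3 and SOD2. None passed in CaCo-2. Where a spot was at 0 on some arrays, its log2 fold change depends on the value set for 0, and the number of arrays above 0 is given beside it. The TNF spot was above 0 on 4 of 5 arrays after TNF and on 2 of 5 control arrays, and its log2 fold change of 0.77 ± 0.56 (SE) had an adjusted p of 0.949 in limma. JUNB, an AP-1 subunit, had a log2 fold change of -1.20 ± 0.53 (SE) at the same adjusted p, with 1 of 5 arrays above 0 after TNF and 4 of 5 before. IER3, an immediate early gene, had a log2 fold change of -0.25 ± 0.44 (SE), with 3 of 5 arrays above 0 after TNF and 4 of 5 before. SOD2, the mitochondrial superoxide dismutase, had one of 0.01 ± 0.02 (SE) and was above 0 on every array that measured it.

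None of the 17 tested gene lists shifted after TNF in CaCo-2 by camera. The NF-kB pathway list, with 15 of 41 genes measured, had a median log2 fold change of 0.01 and an adjusted p of 0.943 in a test whose direction was downward, and 0 members passed, also when adjusted over the list alone. Among 11 measured cytokines and chemokines 0 passed. Of 26 immediate early genes 0 passed over all spots and 2 passed when adjusted over the list alone. By fry without regard to direction, the immediate early list had a p of 0.019, not adjusted over lists. Of its 26 genes 6 were above 0 on every array. The smallest p in that list belonged to ZFP36L1, an mRNA decay factor listed at 0 on all 5 arrays after TNF, and GADD45B, a stress-inducible gene listed at 0 on all 5 control arrays, both at an adjusted p of 0.561 in limma over all spots. The fibroblast and endothelial list had the lowest list p, adjusted to 0.144, with an adjusted p of 0.941 at an estimated correlation.

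**Figure D1:**
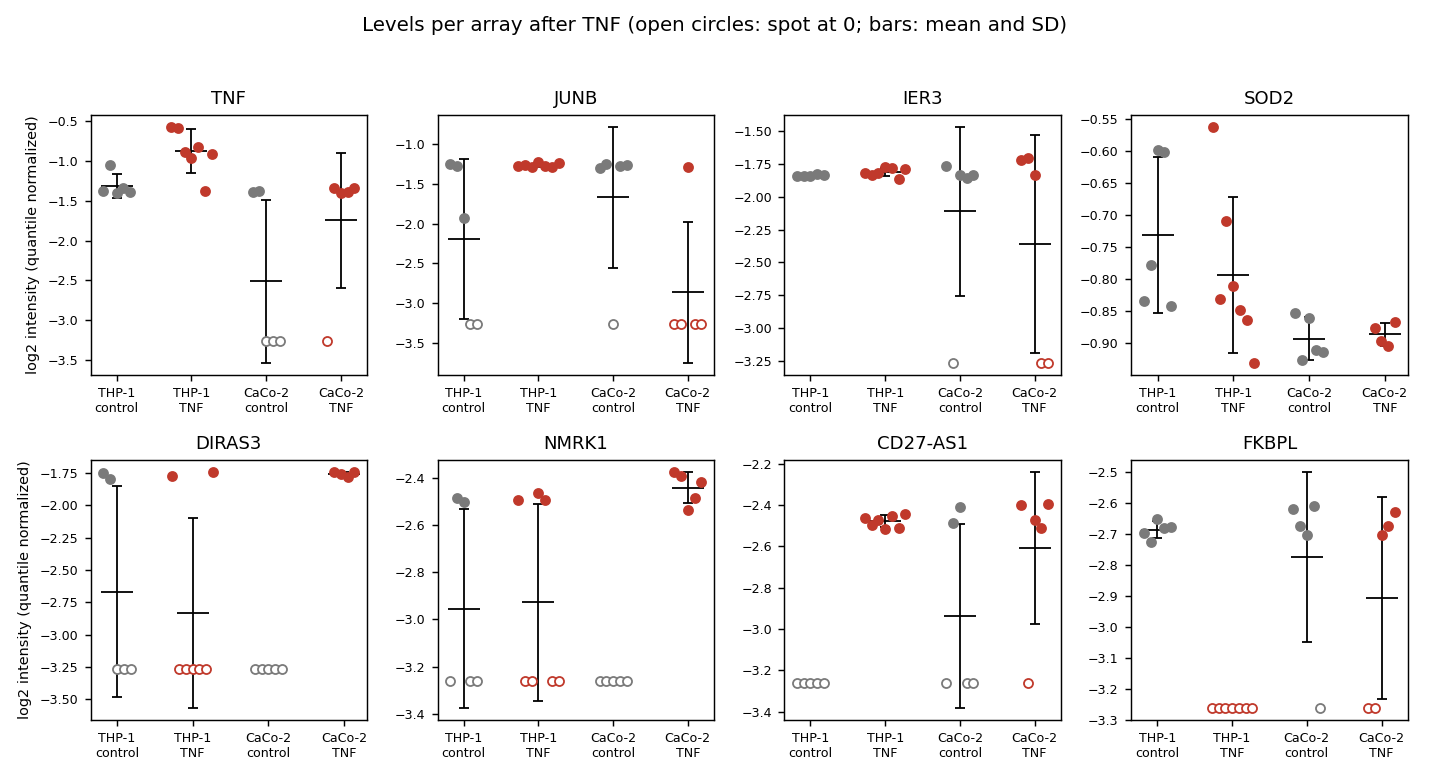
Quantile-normalized log2 intensity (vertical axis) of 8 genes on each array of the 4 groups (horizontal axis); points are arrays, open circles are spots at 0 drawn at the floor, and bars are the mean and SD. For JUNB, 7 of 7 THP-1 TNF arrays and 1 of 5 CaCo-2 TNF arrays were above 0.

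The second comparison asks the same of THP-1 cells. CD27-AS1, an antisense transcript of CD27, read -2.48 ± 0.03 (SD, n = 7) after TNF and was listed at 0 on all 5 control arrays, with an adjusted p of 1.90e-07 in limma. FKBPL, an immunophilin-related protein, read -2.69 ± 0.03 (SD, n = 5) in control cells and was at 0 on all 7 TNF arrays, with an adjusted p of 3.05e-08 in limma. In all, 5 of 34559 spots passed, 3 higher and 2 lower, and 4 of them were at 0 on every array of 1 group. At an unadjusted p under 0.05 there were 1166 spots, against 1728 if p-values were evenly spread. This count was 838 without normalization and 2300 with 2 residual components as covariates, a setting in which counts run high. Among the 9979 spots above 0 on every array of the fit, 0 passed and 299 had an unadjusted p under 0.05. With values at 0 taken as missing, 0 of 26175 passed and 917 had an unadjusted p under 0.05. Neither fit could test the 4 called spots at 0 throughout 1 group.

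The TNF transcript itself was measured on all 12 THP-1 arrays. It read -0.87 ± 0.27 (SD, n = 7) after TNF and -1.31 ± 0.15 (SD, n = 5) before, a log2 fold change of 0.44 ± 0.13 (SE). This missed the threshold at an adjusted p of 0.958 in limma, an adjustment over all spots. Control arrays read from -1.40 to -1.05. TNF replicate 6 read -1.37 and the other TNF arrays from -0.96 to -0.57. JUNB was above 0 on 7 of 7 TNF arrays and 3 of 5 control arrays, with a log2 fold change of 0.93 ± 0.36 (SE). Control replicate 3, the summed column divided by 3, read -1.93, against -1.25 and -1.28 on control replicates 1 and 2. IER3 had a log2 fold change of 0.03 ± 0.02 (SE) and SOD2 one of -0.06 ± 0.07 (SE), both also at an adjusted p of 0.958 in limma. None of the 17 tested lists shifted in THP-1. The NF-kB pathway list had a median log2 fold change near 0, at 0.0040, with a mean of -0.016 and so of the other sign, and an adjusted p of 0.993 by camera. Other members with the smallest p in their lists were PPP1R15A, a phosphatase regulator of the stress response, at 0.47 ± 0.16 (SE) and MCL1, an anti-apoptotic BCL2 relative, at -0.12 ± 0.04 (SE), and neither passed.

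The third comparison asks whether the response to TNF differed between the lines. No spot passed the interaction test in limma, with 1443 spots at an unadjusted p under 0.05 against 1728 if p-values were evenly spread. This count was 869 without normalization and 1936 without CaCo-2 TNF replicate 5. Among the 6401 spots above 0 on every array 134 were under 0.05, and with values at 0 taken as missing 773 of 22507 were, with 0 past the threshold in both. JUNB had an interaction of -2.13 ± 0.63 (SE, log2) at an adjusted p of 0.981 in limma, with 1 of 5 CaCo-2 TNF, 4 of 5 CaCo-2 control and 3 of 5 THP-1 control arrays above 0. TNF had one of 0.33 ± 0.54 (SE), with 2 of 5 CaCo-2 control and 4 of 5 CaCo-2 TNF arrays above 0. None of the 17 tested lists shifted by camera. By fry without regard to direction, the immediate early list had a p of 0.0035, not adjusted over lists. Of its 26 genes 5 were above 0 on every array. Among named genes, the smallest p in either direction belonged to AFDN, a junction adaptor, and to an uncharacterised locus, LOC105373480, with adjusted p of 0.406 and 0.272 in limma. Across all spots, the log2 fold changes of the lines had a Pearson r of -0.0062 and a Spearman rho of 0.0104. Genes are not independent replicates, and 81 of 100 regroupings of arrays within the lines gave an r as far from 0.

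The fourth comparison sets unstimulated CaCo-2 against unstimulated THP-1 cells and checks the labels against cell type markers. LAPTM5, a lysosomal protein of blood cells, read -1.72 ± 0.08 (SD, n = 5) in THP-1 and was at 0 on all 5 CaCo-2 arrays. HLA-E, a class I histocompatibility molecule, read -1.73 ± 0.02 (SD, n = 5) in THP-1 and was at 0 on all 5 CaCo-2 arrays. The adjusted p in limma were 3.06e-07 and 2.92e-08. ELF3, an epithelial transcription factor, passed in both directions and so does not bear on the labels. Its brighter spot read -2.91 ± 0.03 (SD, n = 5) in CaCo-2 and was at 0 on all 5 THP-1 arrays, while another read -3.07 ± 0.04 (SD, n = 5) in THP-1 and was at 0 on all 5 CaCo-2 arrays, with adjusted p of 6.71e-06 and 0.00134 in limma.

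Limma called 155 of 34559 spots between the lines, 97 higher in CaCo-2 and 58 lower, and 4134 spots had an unadjusted p under 0.05. Of the called spots 120 were at 0 on every array of 1 group. Higher in CaCo-2 and at 0 on all 5 THP-1 arrays were spots of REXO1, an RNA exonuclease, at -0.45 ± 0.15 (SD, n = 5), the transporter pseudogenes ATP8B5P, at -0.54 ± 0.25 (SD, n = 5), and ABCC13, and the imprinted gene PEG10 at -2.11 ± 0.07 (SD, n = 5). PXYLP1, PKDCC and CALCOCO2 were also among the 8 largest increases of genes represented by their brightest spot, as was CNOT8, a deadenylase subunit. CNOT8 was above 0 on 1 of 5 THP-1 arrays. Without normalization 5 higher and 21 lower in CaCo-2 passed, and with array medians subtracted 9 higher and 31 lower. All of these were among the 155. Both settings leave each array its own floor for 0. The floor of THP-1 control replicate 3 came from a lowest value of 0.113 divided by 3, against 0.0921 to 0.136 in single columns. Spots at 0 throughout THP-1 thus gained spread there, which bears on calls higher in CaCo-2. Lower in CaCo-2 and at 0 there on all 5 arrays were also ATF6B, PGBD1, TP53BP2, DPY19L1, SLC24A1 and LAIR2, an immunoglobulin-like receptor of leukocytes. Other spots of the same genes mostly showed less: 53 called genes had several spots, and of their 102 spots that were not called 71 differed in the direction of the call, 11 of them at an unadjusted p under 0.05.

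Among the fixed lists, that of monocyte and myeloid markers, with 12 genes measured, ranked lower in CaCo-2 by camera, with an adjusted p of 0.0159 and a median log2 fold change of -0.07, while members went both ways. With an estimated correlation that list had an adjusted p = 0.321, and over spots above 0 on every array one of 0.243. Of its members 1, LAPTM5, passed on its own. Of 7 measured enterocyte markers 1 passed, ELF3 by its brighter spot, against the call of its other spot, and the list had an adjusted p of 0.0851. In the interferon and antigen presentation list 1 of 15 members passed, HLA-E, and B2M, the light chain of class I molecules, had a log2 fold change of -0.26 ± 0.09 (SE) and an adjusted p of 0.339 in limma. Of the 14 line markers fixed in advance, 2 had a spot of their own. VIL1, the brush border protein villin, had a log2 fold change of 0.08 ± 0.04 (SE), and PTPRC, the leukocyte antigen CD45, had one of -0.02 ± 0.05 (SE) while reading above 0 on all 5 arrays of both lines. Their adjusted p in limma were 0.476 and 0.855, so these 2 markers did not tell the lines apart. In the cell cycle list, with 25 genes measured, RRM2, a ribonucleotide reductase subunit, had 0.23 ± 0.05 (SE) and AURKB, a mitotic kinase, 0.11 ± 0.03 (SE), and neither passed over all spots, while 1 member passed when adjusted over the list alone.

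**Figure D2:**
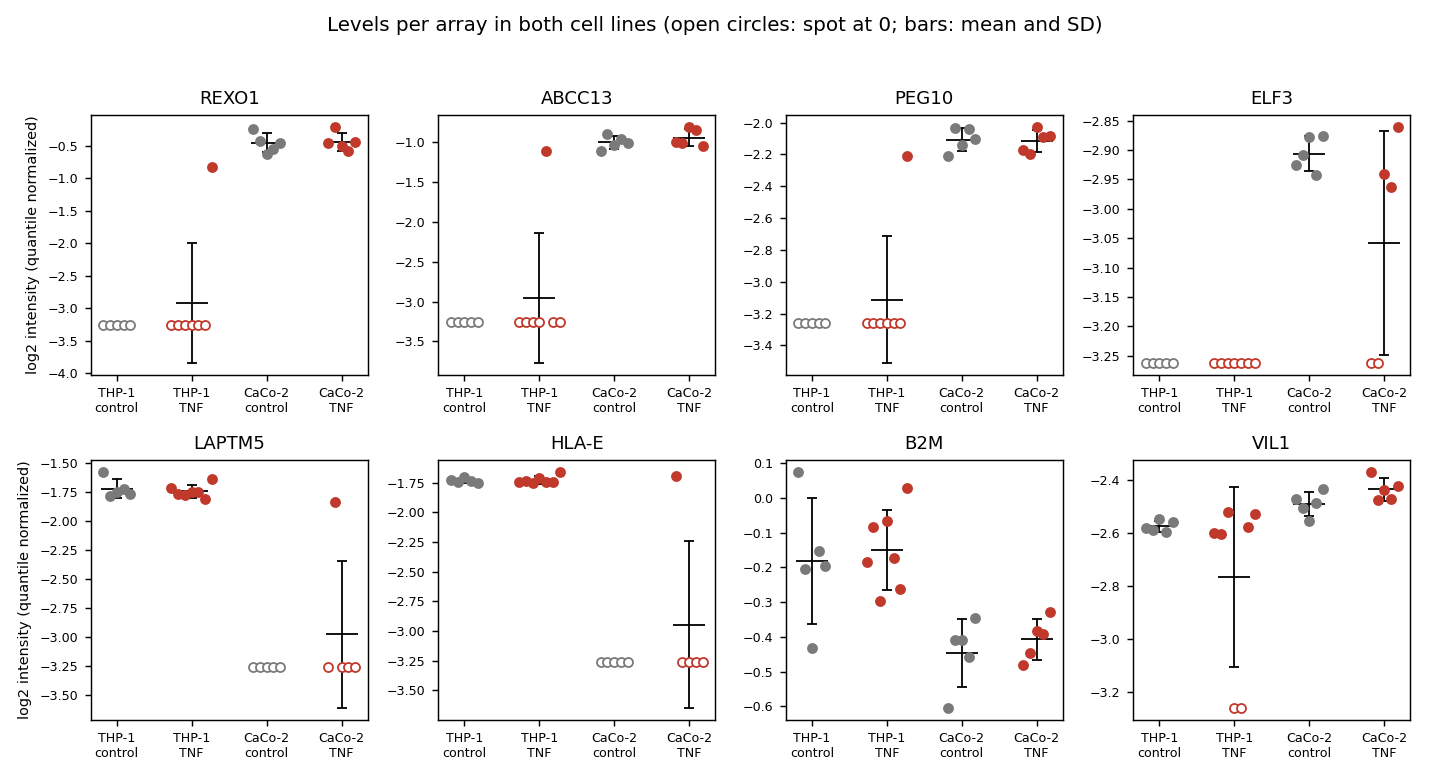
Quantile-normalized log2 intensity (vertical axis) of 8 genes on each array of the 4 groups (horizontal axis); points are arrays, open circles are spots at 0 drawn at the floor, and bars are the mean and SD. LAPTM5 and HLA-E were above 0 on all 12 THP-1 arrays and on 1 of 5 CaCo-2 TNF arrays.

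Over the 6401 spots above 0 on every array, arrays of different lines correlated at a median r of 0.994. Arrays of the same group did so at 0.995. An r across spots is high wherever spots differ much in brightness, and these spots exclude those at 0 throughout 1 line. It therefore does not show how alike the lines are. With only 155 of 34559 spots called even between the lines, few calls after TNF do not show that TNF had no effect. Among the 9074 spots above 0 on every control array the median absolute log2 difference was 0.05, and with only these spots tested 112 passed, a number that 2 of 100 splits of the control arrays reached, the other with 772. This selection leaves out spots at 0 throughout 1 line, which make up most of the 155. With values at 0 taken as missing, 13 of 24758 spots passed between the lines, 4 higher and 9 lower in CaCo-2, and 8 of the 13 were among the 155. That fit, too, could not test spots at 0 throughout 1 line.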

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

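Tests on readings lost to 0, on known TNF targets, on spread at 0 drawn in both directions, on splits over spots above 0 and on the place of single control arrays were chosen after the results they bear on were seen, and the other tests here before. Outlying arrays were searched for in 55 sets of values from groups of 4 to 10 arrays, and 7 were found where chance gives about 2.75. THP-1 TNF replicate 6 had 286 excluded spots against 46 to 135 on the other arrays of its group, and CaCo-2 control replicate 4 had 72 against 98 to 106. The TNF transcript in THP-1 control replicate 2 read -1.05 against -1.40 to -1.34 on the others. ATP8B5P in CaCo-2 control replicate 2 read -0.094 against -0.72 to -0.62. LAPTM5 in THP-1 control replicate 1 read -1.58 against -1.78 to -1.73, DPY19L1 in replicate 3 of that group -1.89 against -1.94 to -1.93, and LAIR2 in its replicate 7 -2.55 against -2.48 to -2.46.

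The TNF calls sat on spots that were at 0 throughout 1 group, apart from 1 of the 5 in THP-1. Chance cannot be excluded for either count: 90 of 100 splits of the CaCo-2 arrays gave at least the 15 calls of the real split, with 129 as the highest of the others, and 47 of 100 splits of the THP-1 arrays gave at least 5, with 17 as the highest. Whether values set to 0 made the calls stays open. As a median of 20 draws, 17 of the 20 stayed when values at 0 were lowered by the spread of dim measured spots. When it was drawn in both directions, 15 stayed. But such a spread is not the uncertainty of a 0 behind which a component was measured. With values at 0 as missing 0 calls were left, but that fit could not test spots at 0 throughout 1 group, so it decides nothing for them. A candidate explanation is readings at 0 although 1 component read near the level, since a median of 3 is 0 where the other components are 0. Of 56 readings at 0 of the called spots on arrays with a summed partner column, 55.4% had 1 component near the level of the other group in that column. For 23 the summed column was 0 too. Readings at 0 of spots over 0.4 were alike in this: the summed column held a value at 822 and was 0 at 609. The share is thus not shown to be particular to the called spots, and why components were 0 is not given. A response of known TNF targets stays open, although the upper bound of the NF-kB list's median log2 fold change was 0.040 in CaCo-2 and 0.035 in THP-1, where 3 and 8 of its 15 measured genes were above 0 on every array: members went both ways, and a median over such members does not exclude a response of some.

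The calls between the lines went beyond other splits, since the real split gave 155 and the highest of the others 102, so that 1 of 100 splits, the real one, reached that number. Of the 155 called spots, 82 differed the same way at an unadjusted p under 0.05 between the TNF-treated arrays of the lines, which are separate arrays, and 1 differed the opposite way, while 12% of all spots had such a p in either direction. That 139 stayed called with values at 0 lowered by the spread of dim spots, and 126.5 as a median with it drawn in both directions, excludes nothing for the same reason as above. With values at 0 as missing 8 stayed, but that fit could not test the 120 called spots at 0 throughout 1 line. The split with 102 exchanges CaCo-2 control replicate 1 with THP-1 control replicate 1. At 432 spots called between the TNF-treated arrays, the THP-1 array lay nearer the CaCo-2 mean at 24.0%, the highest of its group. At the 57 spots above 0 on all arrays it did so at 15.8%, where THP-1 control replicate 3 had 19.3%. It thus lay with THP-1, which leaves an exchange of labels without a partner. The CaCo-2 array lay nearer the CaCo-2 mean at 58.9% of the 432, the lowest of its group, and at 43.9% of the 57, so that its place is not settled. A difference between the lines may underlie part of these calls, but line and any batch that follows the line cannot be told apart.

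The interaction gave 0 calls, which any split reaches, here 100 of 100, so the splits, with 18 as the highest of the others, say nothing about chance there. For the number of lists past the threshold between the lines, 13 of 100 splits gave at least the 1 observed, with 3 as the highest, so chance is not excluded there. Neither is it for the correlation of TNF changes between the lines, where 81 of 100 regroupings gave an r as far from 0 as -0.0062, the farthest of the others being 0.0673.

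CaCo-2 arrays shared a structure that no label names, in which the first residual component held 40.0% of the variance left after the group means. CaCo-2 control replicate 1 scored 0.642 on it, with CaCo-2 TNF replicates 1 and 2 at 0.399 and 0.314, while CaCo-2 control replicate 5 and TNF replicate 6 scored -0.303 and -0.334, and before normalization the first 3 had median log2 levels of -2.61, -2.60 and -2.55 and the others of -3.09 and -3.03. The component was computed over the 7966 spots above 0 on every CaCo-2 array, so it does not need readings at 0. Many calls in other splits did not need them either: over such spots the CaCo-2 split with 129 calls gave 351 and the real one 0. In THP-1 no split gave more than 1, and between the lines the split with 102 gave 772 and the real one 112. The CaCo-2 split does not follow the first component. It set control replicates 2, 3 and 4 and TNF replicates 4 and 5 apart, and so kept the highest and lowest scores named above in 1 arm. Source plate explained 5.04% of the spots' loadings, which argues against plate position as the whole cause. Level explained 0.159%, but quantile normalization removes most dependence on level beforehand, so a scaling cause stays open, as does an unlabelled batch, and no biological explanation was tested.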

How the results depend on the processing

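Counts are given for CaCo-2 TNF (15 in the main setting), THP-1 TNF (5), the interaction (0) and the line comparison (155), with the cause of a change not tested unless named. Without normalization they were 1 in CaCo-2, 1 in THP-1 and 26 between the lines, of which 5 were higher in CaCo-2 and 21 lower, against 97 and 58 in the main setting. Subtracting array medians gave 1 in THP-1 and 40 between the lines, 9 higher and 31 lower, and cyclic loess gave 1 and 39, 10 higher and 29 lower. All calls between the lines under these other normalizations were among the 155. Without normalization or with medians subtracted, the floor of THP-1 control replicate 3 lay below those of the other arrays, since that column was divided by 3. Without the dimmer 50% of spots the counts were 2, 2 and 48. Array weights gave 11 in THP-1 and 337 between the lines. With all 4 groups in 1 fit THP-1 had 0 calls, and CaCo-2 had 12 higher and 9 lower, of which only 5 were among the 15. Gene-level means gave 3 and 2 in CaCo-2 and THP-1, with fewer tests, and the Welch comparison gave 5 in CaCo-2.

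Same-numbered control and TNF arrays did not in general deviate together: their correlations ran from -0.30 to 0.67 over 4 CaCo-2 pairs and from -0.37 to 0.31 over 4 THP-1 pairs, and 1 and 0 control arrays correlated best with their own number. Between arrays of different numbers the highest were 0.73 in CaCo-2, control 5 with TNF 6, and 0.45 in THP-1, control 1 with TNF 8. No fit paired arrays across numbers. With the replicate number as a block, which kept only arrays numbered in both groups, the counts were 3 in CaCo-2, 74 in THP-1 and 9 for the interaction, and 1 list, fibroblast and endothelial markers, passed in the interaction.

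The following settings were chosen after seeing the data. All 33 columns as labelled, close to the planned fit but counting shared readings as replicates, gave 28 in CaCo-2, 43 in THP-1, 11 in the interaction, 1768 between the lines and 0 lists between the lines. The mean of both columns of a pair gave 1 interaction call. Counting the oppositely labelled pair as TNF gave 6 in CaCo-2. Counting it as control gave 9 there and 2 in the interaction. Spots above 0 on every array gave 0 TNF calls in CaCo-2 and 0 in THP-1, by construction without the spots called before, and 0 lists between the lines. Values at 0 as missing gave 0, 0 and 13, again without spots at 0 throughout 1 group. A residual component as covariate gave 299 between the lines, and 2 components gave 12 in THP-1, 298 between the lines and 0 lists there. With these covariates over spots above 0 on every array, the counts were 0 in CaCo-2, 0 in THP-1 and 1019 between the lines with 1 component, and 0, 10 and 1271 with 2, where 0 lists passed between the lines. With 1 component the list that passed there was the NF-kB pathway in place of the myeloid markers. These components come from the residuals they correct, so such counts run high.

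For lists between the lines, where 1 passed in the main setting, 0 passed with an estimated correlation, 3 with fry, 2 with cyclic loess, the second being the cell cycle list, and 2 with gene-level means. The correlation of TNF changes between the lines was 0.288 over the 20 called spots, 0.0427 without normalization and 0.0425 with medians subtracted, with a Spearman rho of 0.254, 0.10 and 0.10 against 0.0104 in the main setting. The 20 spots were picked by these same changes, and most were at 0 throughout 1 group. No regrouping was run for them, so 0.288 says nothing about a shared response. Leaving out each array in turn gave 29 to 51 calls in CaCo-2, 5 to 20 in THP-1, 0 to 12 in the interaction and 175 to 471 between the lines. The highest came without CaCo-2 control replicate 1 in CaCo-2, in the interaction and between the lines, and without THP-1 control replicate 4 in THP-1. Each of the 10 CaCo-2 arrays, when left out, moved the CaCo-2 count by over 1.5 times, as did each THP-1 array the THP-1 count, except TNF replicates 1 and 8. Between the lines CaCo-2 control replicate 4 did so too, at 238. Lists that passed ranged from 0 to 1 in CaCo-2, 0 to 0 in THP-1, 0 to 1 in the interaction and 0 to 2 between the lines. The myeloid list was lost without THP-1 control replicate 4, at an adjusted p of 0.0583. The planned offset at the 10th percentile of all values was not run, because that percentile is 0. No named gene or list reversed, direction being read only where one of the settings passed the threshold; of the comparisons for genes 45 lost and 69 gained a call and 9413 did neither. Signal over background could not be assessed, as no background values were used here.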

Other observations

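Genes in this part were chosen after their values were seen. Between the lines, 41 spots passed the threshold in the same direction both among control arrays and among TNF-treated arrays, 26 higher in CaCo-2 and 15 lower, and 21 of them carry 1 gene symbol. The TNF-treated arrays gave 432 calls between the lines in all, so most of those were not shared with the 155 of the control arrays. Spots lower in CaCo-2 in both belonged to LAPTM5, HLA-E, SRSF5, UXS1, PPT1, MAPK8IP3, CD93, a receptor of myeloid and endothelial cells, and IL6R, the interleukin-6 receptor. The called CD93 spot read -2.14 ± 0.08 (SD, n = 5) in THP-1 controls and -2.12 ± 0.05 (SD, n = 7) after TNF, and was listed at 0 on all 10 CaCo-2 arrays, with adjusted p of 3.13e-06 and 7.19e-08 in limma. Neither of the other CD93 spots passed among controls: one, at 0 on all 5 CaCo-2 control arrays, had an adjusted p of 0.146 in limma. The other was above 0 on all arrays of both lines, with a log2 difference of -0.094 ± 0.04 (SE) among controls at an adjusted p of 0.441 in limma. IL6R read -2.60 ± 0.06 (SD, n = 5) and -2.64 ± 0.06 (SD, n = 7) in THP-1 and was also at 0 on all 10 CaCo-2 arrays, with adjusted p of 1.50e-05 and 6.38e-06 in limma. Spots higher in CaCo-2 in both belonged to REXO1, ABCC13, PEG10, CAVIN1, STARD10, IGF2BP1, HDAC7, TMEM98, PARG, BCAR3, PCNX4, the actin regulator CTTN, and KRTCAP3. The called CTTN spot read -2.91 ± 0.09 (SD, n = 5) in CaCo-2 controls and KRTCAP3 -2.93 ± 0.04 (SD, n = 5), and both were at 0 on all 12 THP-1 arrays. Another REXO1 spot had a log2 difference of -0.11 ± 0.19 (SE) among controls, and a CAVIN1 spot above 0 on every control array of both lines had one of -0.0011 ± 0.03 (SE), so that a higher level of these genes in CaCo-2 is not shown. Another CTTN spot was above 0 on 4 of 5 THP-1 control arrays and did not pass. Of the 53 genes called among controls that have several spots, 1 had over 1 spot called. A call of 1 spot thus does not show a difference of the gene, for the other genes listed here as well.

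Among the 112 spots that differed between the control arrays and were above 0 on every one of them, 74 were higher in CaCo-2 and 38 lower, and the median absolute log2 difference was 0.20. This test of 9074 spots was chosen after seeing the data, and only 16 of the 112 also passed over all spots, KRT8P12 and PPT1 among them but not SPINT2, UHRF1 or SRGN. An exchange of CaCo-2 control replicate 1 with THP-1 control replicate 1 gave 772 calls in this test, so that structure among the arrays bears on it. The direction was the same in the TNF-treated arrays for 108, at an unadjusted p under 0.05 for 78. The largest named difference was KRT8P12, a pseudogene of keratin 8, at 0.79 ± 0.09 (SE, adjusted p of 0.00340 in limma). SPINT2, an epithelial protease inhibitor, was higher in CaCo-2 by 0.30 ± 0.05 (SE) on the log2 scale, and UHRF1, a DNA methylation cofactor, by 0.31 ± 0.05 (SE). PPT1, a lysosomal thioesterase, had -0.33 ± 0.03 (SE), and SRGN, the proteoglycan of blood cell granules, -0.30 ± 0.06 (SE).

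The pair of columns that carries 1 set of readings under both a CaCo-2 control and a CaCo-2 TNF label could not be assigned, and entered only the alternative settings.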
